A study of Mus musculus with 47 samples.

How the data were processed

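Gene expression was measured on Affymetrix mouse arrays from 2000 sorted adult bone marrow cells per sample, with RNA amplified by dual amplification, per the series design text. The deposited values are intensity values on a linear scale, 1 per probe set and array, calculated by the authors with RMA per the series design text. The software, its version and how arrays were scaled to each other are not given in the sources used here. Array medians ran from 13.8 to 16.9. Values are relative within an array, so a difference in total RNA per cell is not measured. Amplified RNA of few cells adds spread that the replicates carry.

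Log2 of the deposited values was taken with no pseudocount. The table held 45101 probe sets. The platform annotation listed 35890 of them, 34958 with 1 gene symbol and 932 with several, and 9211 were not listed; only those with 1 symbol were named. Of 18194 genes, 9012 had several probe sets, and the brightest over all arrays stood for the gene. Where the probe sets of a named gene differ in sign, their range is given with it. The 13949 genes with at least 1 group mean over the median of all log2 values (3.889) were tested. Groups were taken from the sample labels, and comparisons and tests were set before the data were examined, as were the 30 gene lists (427 genes, 377 of them tested).

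A linear model with 17 group means was fitted to all 47 arrays (30 residual degrees of freedom) with limma 3.58.1 in R 4.3.3, and comparisons were tested with moderated statistics, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison and at least 2-fold. Lists were tested with camera with an estimated correlation between genes, adjusted over the lists of a comparison, and a preset correlation of 0.01 was the alternative. Lineage signatures came from the same arrays. With 200 changed genes simulated, the fit recovered, by comparison, 76 to 99% of those changed by 1.5 (log2) and 98 to 100% by 3. It called 0 to 9 unchanged genes and gave none a wrong direction. Real error rates were not tested.

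Named genes come from a rule set before the data were examined. It takes the 8 largest rises and the 8 largest falls among called genes with a plain symbol and no overlap between arrays of the groups, members of the fixed lists that fit the comparison in order of size, and called lineage transcription factors. Which lists fit a comparison was decided after the list tests had been seen, and which of the rule's genes to print after their values had been seen. Mostly genes with a textbook function were printed, and those whose call ended when 1 array was left out were dropped, except where that value is given. Immunoglobulin, T cell receptor, granzyme, Klra and Ly6 genes are open to cross-hybridisation.

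Alternatives set beforehand were the mean of all probe sets, no filter and a stricter filter (over 5.968) on dim probe sets, quantile normalization again, centring each array on its median, a floor of 16, array weights, a trended robust spread, the replicate number as a block, fits of the compared groups alone and leaving out each array in turn. The iteration for array weights stopped before it converged. Classes of arrays by Xist (over 7) and Eif2s3y (over 5), all fits that use them, the B signature without ProB, and the comparisons of PreB with CLP and GM with LMPP were chosen after seeing the data. The labels give no sex of the animals and no batch.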

Results

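Gene expression was measured on 47 arrays of cells sorted from adult bone marrow of C57Bl6 mice, in 17 groups that the labels name LTHSC, STHSC, LMPP, MkE, PreCFUE, CFUE, ProE, MkP, GMP, GM, CLP, ProB, PreB, IgM+SP, ETP, CD4 and NKmature. In common use these names stand for stages of blood formation, from stem cells (LTHSC, STHSC) through progenitors of several or single lineages to lymphocytes. The labels spell out none of them and give no sorting markers. LMPP had 5 arrays, MkE and PreB had 4 each, PreCFUE, CFUE, ProE, MkP, GMP and ETP had 3 each, and the other groups had 2 each. The labels call the arrays of a group biological replicates and name no animals or pools, so p-values measure the spread between these arrays, whatever its source. Each array was made from 2000 cells, and the number of arrays limits the precision of every value.

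Upper quartiles of intensity ran from 50.2 to 75.7. Both CLP arrays had the lowest (50.2, 50.7) and the highest median (16.9), so array scale may add to differences from CLP. Over the 13949 genes tested, replicates correlated at 0.928 to 0.997 and arrays of different groups at 0.721 to 0.983, and 46 of the 47 arrays had their highest correlation with an array of their own group. Among the groups, 12598 of 13949 genes differed by limma's moderated F-test (90.3%). Transcripts linked to the sex of the animal split the arrays. The X-inactivation transcript Xist without the Y-linked Eif2s3y was found on 21 arrays, Eif2s3y without Xist on 19, and both on 7 (ETP replicates 2 and 3, LMPP replicates 3 to 5, and both NKmature arrays). Both groups of a comparison lay in 1 such class in 4 comparisons, shared a class in 6 and shared none in 7, where whatever goes with the sex of the animals, a batch included, cannot be told apart from the group. Those 7 were MkE with LTHSC, LMPP with MkE, ProE with CFUE, GM with GMP, ProB with CLP, CD4 with ETP and NKmature with CLP. Values after a gene name are the log2 difference of group means, first group minus second, ± the standard error from limma's fit of all 47 arrays, and p is adjusted by the Benjamini-Hochberg method. Medians beside a gene list are those of the log2 differences of its measured members. All 30 lists were tested in all 17 comparisons, and 46 of the 510 tests passed by camera with an estimated correlation (166 with a preset one). The p beside a list is camera's with the estimated one, adjusted over the 30 lists, with its value where leaving out 1 array changed the call or another setting, the replicate block aside, ended it. Counts adjusted over the list alone are given where they differ from those over all genes. Differences of genes whose level in a group lies under the filter level of 3.889 (log2) rest on dim values there.

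**Figure D1:**
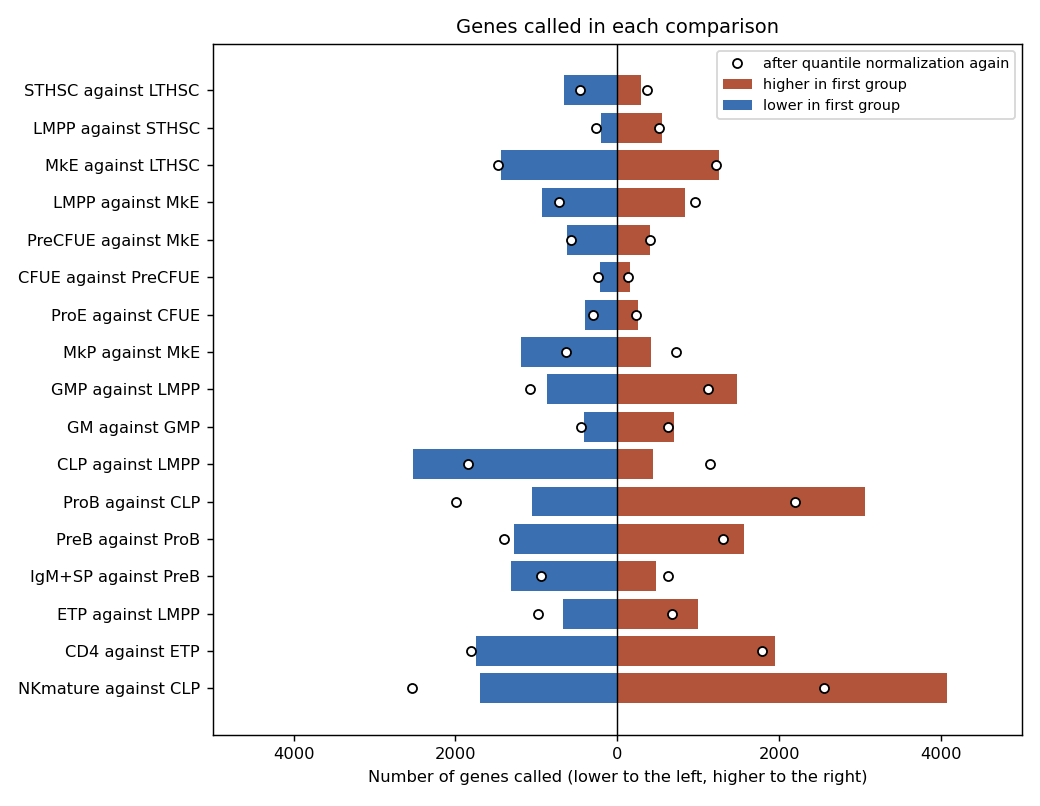
Genes called in each of the 17 comparisons by limma (Benjamini-Hochberg adjusted p below the 0.05 threshold and at least 2-fold), as bars to the right for genes higher in the first group and to the left for genes lower, with circles for the same counts after the arrays were quantile normalized again. The count ran from 370 genes for CFUE against PreCFUE to 5756 for NKmature against CLP, and in CLP against LMPP the higher genes went from 438 to 1142 after quantile normalization.

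The comparison of STHSC (2 arrays) with LTHSC (2 arrays) addresses what separates the stem cell groups. Genes of cell division were higher in STHSC, among them the midbody protein Cep55 (4.19 ± 0.51, adjusted p = 4.2e-07), the mitotic cyclin Ccna2 (3.73 ± 0.52, 1.94 without LTHSC replicate 1), the spindle protein Nusap1 (3.59 ± 0.42, 2.25 without LTHSC replicate 1) and Prc1 (3.43 ± 0.52, 1.81 without LTHSC replicate 1). Genes known from long-term stem cells were lower, including von Willebrand factor Vwf (-4.24 ± 0.50), the cell cycle inhibitor Cdkn1c (-3.15 ± 0.28, adjusted p = 4.8e-10) and the homeobox gene Hoxb5 (-3.11 ± 0.23). The carbonic anhydrase Car1 (-5.33 ± 0.61) was also lower. In all, 287 genes were called higher and 663 lower in STHSC.

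In the stem cell list, 16 of 18 members were lower (median -2.09, adjusted p = 6.7e-05), with Mllt3 (-3.02 ± 0.41) among them. Of the mitosis list, 18 of 19 members were higher (19 adjusted over the list alone, median 2.50, adjusted p = 0.0068, median 1.54 without LTHSC replicate 1). In the DNA replication list, 7 of 21 members were higher (9 adjusted over the list alone, median 0.93, adjusted p = 0.00047, median 0.59 without LTHSC replicate 1), with the ribonucleotide reductase subunit Rrm2 (2.52 ± 0.41, 1.29 without LTHSC replicate 1) and thymidine kinase Tk1 (2.15 ± 0.42) among them. The mast cell and basophil list, in which 3 of 6 members were higher (median 1.01, adjusted p = 0.031 but 0.12 with probe set means and 0.057 to 0.17 without LTHSC replicate 2 or STHSC replicate 1 or 2, median 0.58 without STHSC replicate 1), included Cpa3 (1.67 ± 0.35). In the HoxA and Meis list, 3 of 9 members were lower (median -0.87, adjusted p = 0.031 but 0.16 with the stricter filter and 0.063 to 0.098 without LTHSC replicate 1 or STHSC replicate 2, median -0.54 without STHSC replicate 1). The granule protease Ctsg (3.66 ± 0.66) was higher. In the primary granule list, 4 of 9 members were higher (median 0.13, adjusted p = 0.18, median 0.26 to 0.34 without LTHSC replicate 1 or 2 or STHSC replicate 2). Of the erythroid list, 10 of 20 members were lower (median -0.94, adjusted p = 0.24 but 0.039 without LTHSC replicate 1, median -1.53 without LTHSC replicate 1 and -0.35 without LTHSC replicate 2), and its mean level was 6.35 and 7.51 on the LTHSC arrays and 5.56 and 6.01 on the STHSC arrays. The T lineage factor Gata3 (-1.83 ± 0.29) was lower. After quantile normalization again, 44.5% of the called genes were higher, against 30.2% without it. With a fit of these 4 arrays alone, limma called 1 gene higher and 2 lower, so the counts rest on the spread of the other groups. Without STHSC replicate 1, 157 genes were higher and 220 lower, and without LTHSC replicate 2, 413 were lower.

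Between LMPP (5 arrays) and STHSC (2 arrays), genes of early lymphoid cells were higher and genes of stem cells and megakaryocytes lower. The terminal transferase Dntt (4.84 ± 0.42, adjusted p = 1.7e-10), which adds nucleotides at rearranging antigen receptor genes, the inhibitory receptor Btla (3.97 ± 0.42), the chromatin organiser Satb1 (3.73 ± 0.36) and Notch1 (2.81 ± 0.28) were higher in LMPP. The mast cell protease Cpa3 (-4.66 ± 0.30, adjusted p = 7.9e-14), the monoamine transporter Slc18a2 (-5.24 ± 0.34), platelet factor Pf4 (-4.35 ± 0.80) and the platelet integrin Itga2b (-4.17 ± 0.27) were lower. In all, 547 genes were called higher and 209 lower in LMPP.

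Of the early lymphoid list, 9 of 16 members were higher (12 adjusted over the list alone, median 1.58, adjusted p = 0.00035). In the stem cell list, 7 of 18 members were lower (median -0.82, adjusted p = 0.0022, median -0.50 without STHSC replicate 2), with Gata2 (-2.72 ± 0.24) and Pdzk1ip1 (-2.84 ± 0.22) among them. Of the megakaryocyte and platelet list, 9 of 19 members were lower (median -0.91, adjusted p = 0.01 but 0.086 without STHSC replicate 2, median -0.39 without STHSC replicate 2). For mast cells and basophils, 2 of 6 members were lower (median -0.61, adjusted p = 0.015 but 0.065 with probe set means and 0.071 without STHSC replicate 1, median -0.39 without STHSC replicate 1). Of the list for antigen presentation by MHC class II, 4 of 10 members were higher (5 adjusted over the list alone, median 1.18, adjusted p = 0.16), with cathepsin Ctss (3.38 ± 0.30) among them. Erythroid transcripts included Gata1 (-2.51 ± 0.28), and in their list 5 of 20 members were lower (6 adjusted over the list alone, median -0.35, adjusted p = 0.34). The myeloid factor Irf8 (3.78 ± 0.35) was higher. In the immediate early and stress list, 1 of 14 members was lower (7 adjusted over the list alone, median -1.99, adjusted p = 0.66, median -1.30 without LMPP replicate 4 and -1.25 without LMPP replicate 5), and its mean level on the LMPP arrays was 9.90, 9.47 and 9.50 in replicates 1 to 3 against 5.14 and 5.09 in replicates 4 and 5. Counts were 196 higher and 130 lower with the LMPP arrays without Xist, which share the class of STHSC, 990 and 554 with those with Xist, and 330 higher with the sex class as a block. Without STHSC replicate 1, 181 genes were higher, and with a fit of the arrays of these groups alone, 152 were higher and 74 lower.

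MkE (4 arrays) carried much less of the stem cell genes than LTHSC (2 arrays) and more of several erythroid genes. The erythroid transcription factors Klf1 (3.39 ± 0.45, adjusted p = 2.2e-07, 1.91 without LTHSC replicate 1) and Gata1 (3.19 ± 0.28) and the ammonium transporter Rhag (3.26 ± 0.32, 2.10 without LTHSC replicate 1) of the red cell membrane were higher in MkE. The endothelial protein C receptor Procr (-7.14 ± 0.36), the transcription factor Hlf (-5.92 ± 0.23, adjusted p = 3.7e-21) and the guanine exchange factor Fgd5 (-5.55 ± 0.29) were lower. In all, 1253 genes were called higher and 1437 lower in MkE.

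Of the stem cell list, 15 of 18 members were lower (median -3.86, adjusted p = 0.00016). In the HoxA and Meis list, 5 of 9 members were lower (median -1.15, adjusted p = 0.011 but 0.41 with the sex block), with Hoxb5 (-3.94 ± 0.20) among them. Of the DNA replication list, 9 of 21 members were higher (median 0.84, adjusted p = 0.044 but 0.12 to 0.43 with probe set means, the stricter filter, centring or the sex block and 0.05 to 0.092 without LTHSC replicate 1 or MkE replicate 2, 3 or 4, median 0.37 with probe set means), with the helicase subunit Mcm4 (2.31 ± 0.41) among them. Mitosis genes such as Ccna2 (2.79 ± 0.45, 1.00 without LTHSC replicate 1, 4.58 without LTHSC replicate 2) went the same way. Of their list, 15 of 19 members were higher (median 1.58, adjusted p = 0.33, median 0.39 without LTHSC replicate 1 and 2.77 without LTHSC replicate 2). In the erythroid list, 8 of 20 members were higher (8 higher and 1 lower adjusted over the list alone, median 0.63, adjusted p = 0.33, median 0.30 without LTHSC replicate 1 and 1.34 without LTHSC replicate 2), and its mean level was 6.35 and 7.51 on LTHSC replicates 1 and 2 and 7.87 to 8.09 on the MkE arrays. Of the early lymphoid list, 7 of 16 members were lower (8 adjusted over the list alone, median -1.01, adjusted p = 0.21, median -0.65 without LTHSC replicate 1), with Dntt (-2.97 ± 0.44) and Lsp1 (-4.30 ± 0.30) among them. The platelet genes Mmrn1 (-5.10 ± 0.41) and Vwf (-3.00 ± 0.43) were lower. Of their list, 6 of 19 members were lower (median -0.73, adjusted p = 0.33). The immediate early factors Jun (-8.26 ± 1.37, adjusted p = 1.1e-05) and Fos (-7.54 ± 1.54) were lower, and in their list 12 of 14 members were lower (median -4.39, adjusted p = 0.33). Gfi1 (-3.67 ± 0.38) and Gata3 (-2.79 ± 0.25) were lower. All MkE arrays and no LTHSC array carried Xist (6.75 ± 1.63), and with the sex class as a block 2973 genes were lower. Without LTHSC replicate 1, 719 genes were higher.

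LMPP (5 arrays) and MkE (4 arrays) divided along lymphoid against erythroid genes. The lymphoid Dntt (7.33 ± 0.34, adjusted p = 1.1e-19), the progenitor antigen Cd34 (5.92 ± 0.19), the cytokine receptor Flt3 (5.10 ± 0.27) and the interferon regulatory factor Irf8 (4.90 ± 0.28) were higher in LMPP. The erythroid Car1 (-8.53 ± 0.41, adjusted p = 2.4e-19), the water channel Aqp1 (-7.01 ± 0.29), Klf1 (-6.37 ± 0.35), Gata1 (-5.66 ± 0.22) and Gfi1b (-3.79 ± 0.23) were lower. In all, 835 genes were called higher and 926 lower in LMPP.

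Of the early lymphoid list, 14 of 16 members were higher (median 3.04, adjusted p = 0.00018). Of the erythroid list, 14 of 20 members were lower (median -1.79, adjusted p = 0.018 but 0.12 with the sex block). Granule genes that were higher included Mpo (4.98 ± 0.61), Ctsg (3.79 ± 0.45) and Prtn3 (3.20 ± 0.38). In the primary granule list, 4 of 9 members were higher (median 0.50, adjusted p = 0.16). For monocytes and macrophages, 7 of 17 members were higher (median 0.26, adjusted p = 0.16, median 0.13 without MkE replicate 3), with Klf4 (4.13 ± 0.60) among them. The class II gene H2-Aa (3.94 ± 0.44) was higher, and in that list 5 of 10 members were higher (median 1.37, adjusted p = 0.16). In the mitosis list, 17 of 19 members were higher (median 1.46, adjusted p = 0.26). Of the haem synthesis and iron list, 6 of 15 members were lower (median -0.67, adjusted p = 0.27), with biliverdin reductase Blvrb (-3.87 ± 0.29) and Alad (-2.87 ± 0.34) among them. The immediate early list, in which 12 of 14 members were higher (median 2.32, adjusted p = 0.29), was low on LMPP replicates 4 and 5 as given above. With the sex class as a block, 2428 genes were higher and 1831 lower, and the groups share no class.

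PreCFUE (3 arrays) had more of the DNA replication genes than MkE (4 arrays) and less of the cell cycle inhibitors and of several platelet and stem cell genes. The Rhesus antigen Rhd (3.05 ± 0.33, adjusted p = 5.2e-09), the claudin Cldn13 (3.01 ± 0.31) of mouse erythroid cells, the transferrin receptor Tfrc (1.82 ± 0.26) and the sphingosine kinase Sphk1 (5.38 ± 0.37) were higher in PreCFUE. Meis1 (-4.16 ± 0.27, adjusted p = 1.4e-14), the platelet signalling protein Plek (-4.05 ± 0.34), Itga2b (-2.76 ± 0.25) and the cyclin Ccng2 (-4.30 ± 0.31) were lower. In all, 400 genes were called higher and 620 lower in PreCFUE.

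Of the list of cell cycle inhibitors and quiescence genes, 6 of 16 members were lower (median -0.91, adjusted p = 0.007), with the antiproliferative Btg1 (-2.24 ± 0.30) and the inhibitor Cdkn2d (-1.72 ± 0.31) among them. Of the DNA replication list, 7 of 21 members were higher (median 0.67, adjusted p = 0.013 but 0.15 with probe set means), with Cdc6 (1.76 ± 0.32) and Rrm2 (1.66 ± 0.32) among them. In the erythroid list, 6 of 20 members were higher and 1 lower (median 0.46, adjusted p = 0.23). Of the haem synthesis and iron list, 5 of 15 members were higher (median 0.87, adjusted p = 0.23). Of the platelet list, 6 of 19 members were lower (median -0.66, adjusted p = 0.098). Of the stem cell list, 5 of 18 members were lower (median -0.43, adjusted p = 0.13), with Slamf1 (-2.37 ± 0.19) and Gata2 (-2.17 ± 0.22) among them. Mitosis genes included Bub1 (1.90 ± 0.29) and Aurkb (1.61 ± 0.34). Of their list, 10 of 19 members were higher (12 adjusted over the list alone, median 1.15, adjusted p = 0.23). In the mitochondrial respiration list, 3 of 17 members were higher (median 0.73, adjusted p = 0.052). The transcription factor Fli1 (-2.76 ± 0.31) was lower.

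Between CFUE and PreCFUE (3 arrays each), several genes of haem synthesis were higher in CFUE, though neither that list nor the erythroid one passed. Cldn13 (2.06 ± 0.33, adjusted p = 3.6e-05), the coproporphyrinogen oxidase Cpox (1.48 ± 0.26) and the mitochondrial glycine carrier Slc25a38 (1.51 ± 0.31) were higher. The angiotensin receptor Agtr1a (3.45 ± 0.24, adjusted p = 2.7e-13) was higher too. Vimentin Vim (-4.23 ± 0.24), Plac8 (-3.90 ± 0.20) and Apoe (-3.15 ± 0.36) were lower. In all, 150 genes were called higher and 220 lower in CFUE.

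Of the haem synthesis and iron list, 5 of 15 members were higher (median 0.75, adjusted p = 0.47), with uroporphyrinogen synthase Uros (1.36 ± 0.28) and Abcb10 (1.32 ± 0.26) among them. In the erythroid list, 3 of 20 members were higher (median 0.26, adjusted p = 0.47). Of the stem cell list, 3 of 18 members were lower (median -0.10, adjusted p = 0.5, median -0.06 without CFUE replicate 1), with Meis1 (-2.41 ± 0.28), Gata2 (-1.48 ± 0.24) and Slamf1 (-1.17 ± 0.21) among them, and Fli1 (-1.70 ± 0.33) was lower. The mitosis list had a median log2 difference of 0.33 (camera adjusted p = 0.71) and the DNA replication list 0.22 (adjusted p = 0.5). Without PreCFUE replicate 1, 297 genes were higher, and with array weights 245 were.

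ProE (3 arrays) carried several erythroid genes at higher levels than CFUE (3 arrays). The anion exchanger of the red cell membrane, Slc4a1 (8.69 ± 0.63, adjusted p = 6e-13, its probe sets from -0.04 to 8.69), and the erythroid aminolevulinate synthase Alas2 (5.19 ± 0.82), the first enzyme of haem synthesis, were higher, and the mitochondrial iron carrier Slc25a37 (1.97 ± 0.35) was higher. Myc (-1.89 ± 0.26), the homeobox gene Hhex (-3.27 ± 0.25, adjusted p = 3.4e-12) and the proteasome subunit Psmb8 (-2.63 ± 0.35) were lower. In all, 248 genes were called higher and 396 lower in ProE.

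Of the DNA replication list, 2 of 21 members were higher (4 adjusted over the list alone, median 0.51, adjusted p = 0.047 but 0.087 to 0.25 with probe set means, the stricter filter, centring or the sex block and 0.053 to 0.06 without CFUE replicate 1 or 3 or ProE replicate 1 or 2, median 0.93 with the sex block), with the polymerase subunit Pola1 (1.34 ± 0.27) among them. In the erythroid list, 4 of 20 members were higher (median 0.43, adjusted p = 0.31), with ankyrin Ank1 (1.16 ± 0.24) among them. Of the haem synthesis and iron list, 5 of 15 members were higher and 1 lower (median 0.50, adjusted p = 0.51), with Uros (1.92 ± 0.28) among them. In the ribosome biogenesis list, 3 of 20 members were lower (median -0.39, adjusted p = 0.11), with Rrp9 (-1.20 ± 0.26) among them. The proliferation marker Mki67 (1.15 ± 0.29) was higher. Of the mitosis list, 4 of 19 members were higher (median 0.61, adjusted p = 0.68). The factor Myb (-1.07 ± 0.19) was lower. The immediate early gene Fos (5.60 ± 1.45) was higher. Transcripts linked to sex differed, with Eif2s3y (6.84 ± 1.05, adjusted p = 1.5e-05, its probe sets from -0.20 to 6.84) and Uty (2.91 ± 0.41) higher, and in that list 3 of 4 members were higher and 1 lower (median 2.90, adjusted p = 0.047 but 0.067 to 0.73 with probe set means, the stricter filter, centring, the floor or the sex block and 0.053 to 0.06 without CFUE replicate 1 or 3 or ProE replicate 1 or 2, median 1.08 with probe set means, median 1.60 with the floor, median 0.18 with the sex block). The groups share no sex class, and with the class as a block 1398 genes were higher and 892 lower.

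MkP (3 arrays) had more of the platelet genes than MkE (4 arrays) and less of several erythroid ones. The platelet integrin Itgb3 (6.21 ± 0.32, adjusted p = 1.2e-17), platelet factor Pf4 (6.18 ± 0.73), multimerin Mmrn1 (5.11 ± 0.36), P-selectin Selp (4.28 ± 0.26) and Vwf (4.19 ± 0.38, adjusted p = 6.4e-11) were higher in MkP. The erythroid Car1 (-5.83 ± 0.46), Tspo2 (-4.44 ± 0.29), Rhag (-4.25 ± 0.28) and Klf1 (-2.98 ± 0.40) were lower, as was the lectin Lgals1 (-5.72 ± 0.30). In all, 413 genes were called higher and 1193 lower in MkP.

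Of the megakaryocyte and platelet list, 14 of 19 members were higher (median 2.12, adjusted p = 0.0013). In the erythroid list, 7 of 20 members were lower (median -0.92, adjusted p = 0.23). Of the haem synthesis and iron list, 7 of 15 members were lower (median -0.57, adjusted p = 0.45, median -0.89 without MkE replicate 1 and -0.99 without MkP replicate 2). Stem cell genes that were higher included Fhl1 (4.23 ± 0.24), Mecom (2.48 ± 0.36) and Esam (2.17 ± 0.21), and in that list 6 of 18 members were higher (median 0.62, adjusted p = 0.14). In the mitosis list, 7 of 19 members were higher (8 adjusted over the list alone, median 0.89, adjusted p = 0.41). In the ribosome biogenesis list, 4 of 20 members were lower (median -0.56, adjusted p = 0.23), with Myc (-1.55 ± 0.24) among them. Fli1 (2.12 ± 0.31) was higher and Myb (-1.32 ± 0.18) lower. The percentage of called genes that were higher went from 25.7% to 53.3% with quantile normalization again (728 higher, 638 lower), which moved the median of all genes by 0.128, while centring each array on its median moved it by -0.119.

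GMP (3 arrays) had more of the granule genes than LMPP (5 arrays) and less of the lymphoid, class II and stem cell genes. The granulocyte progenitor gene Ms4a3 (7.15 ± 0.25, adjusted p = 4.6e-23), the granule proteases Ctsg (4.24 ± 0.49) and Elane (3.60 ± 0.26), haptoglobin Hp (5.94 ± 0.34) and the coagulation factor F13a1 (5.64 ± 0.44, adjusted p = 6e-13) were higher in GMP. Dntt (-7.66 ± 0.37), Flt3 (-4.24 ± 0.29), Hlf (-3.84 ± 0.19), Meis1 (-3.74 ± 0.25) and the chemokine Ccl3 (-4.93 ± 0.80) were lower. In all, 1480 genes were called higher and 870 lower in GMP.

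Of the primary granule list, 8 of 9 members were higher (median 2.86, adjusted p = 0.0066). For mast cells and basophils, 5 of 6 members were higher (median 1.73, adjusted p = 0.019), with Cpa3 (5.35 ± 0.26) and Ms4a2 (4.59 ± 0.26) among them. Of the early lymphoid list, 13 of 16 members were lower (median -1.93, adjusted p = 0.005). Of the MHC class II list, 7 of 10 members were lower (median -2.04, adjusted p = 0.047 but 0.094 with probe set means and 0.051 to 0.067 without GMP replicate 3 or LMPP replicate 4 or 5). The stem cell list, in which 9 of 18 members were lower (median -0.93, adjusted p = 0.019 but 0.05 with the sex block), included Procr (-3.17 ± 0.30). In the list of cell cycle inhibitors and quiescence genes, 6 of 16 members were lower (median -0.95, adjusted p = 0.012), with Egr1 (-4.83 ± 0.85) and Klf2 (-3.05 ± 0.71) among them, of which Egr1 is also in the immediate early list that was low on LMPP replicates 4 and 5. Of the plasmacytoid dendritic list, 4 of 8 members were lower (median -0.81, adjusted p = 0.047 but 0.06 to 0.17 with probe set means, quantile normalization, the floor or the sex block and 0.051 to 0.073 without GMP replicate 1 or 3 or LMPP replicate 4 or 5), with Tcf4 (-2.99 ± 0.21) among them. In the HoxA and Meis list, 4 of 9 members were lower (median -0.70, adjusted p = 0.047 but 0.05 to 0.065 with probe set means, the stricter filter, quantile normalization or the sex block and 0.051 to 0.064 without GMP replicate 3 or LMPP replicate 4 or 5). Monocyte genes included Ms4a6c (4.00 ± 0.45) and the receptor Csf1r (2.23 ± 0.54). Of their list, 6 of 17 members were higher (median 0.07, adjusted p = 0.38, median 0.11 to 0.24 with 1 array left out). The myeloid factors Cebpa (1.55 ± 0.18), Irf8 (1.36 ± 0.31) and Gfi1 (1.36 ± 0.32) were higher. Of the called genes, 63.0% were higher, and 50.8% with quantile normalization again. Counts were 1793 higher and 1206 lower with the LMPP arrays without Xist, which share the class of GMP, and 1406 and 782 with those with Xist.

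The arrays labelled GM (2) carried more lymphoid and stem cell transcripts than those labelled GMP (3) and less of several granule genes. Dntt (7.11 ± 0.46, adjusted p = 2.5e-14), Flt3 (3.69 ± 0.37), Meis1 (3.36 ± 0.32), Hlf (3.04 ± 0.24) and the interleukin receptor Il7r (2.98 ± 0.70, adjusted p = 0.0027) were higher in GM. Ms4a3 (-3.59 ± 0.31), Gda (-5.13 ± 0.56), the stem cell antigen Prom1 (-5.06 ± 0.37), the lectin Clec4a2 (-5.27 ± 0.40) and Klf4 (-4.02 ± 0.82) were lower. In all, 698 genes were called higher and 411 lower in GM.

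Of the early lymphoid list, 9 of 16 members were higher (10 adjusted over the list alone, median 1.24, adjusted p = 0.0069). Of the stem cell list, 7 of 18 members were higher (8 adjusted over the list alone, median 0.98, adjusted p = 0.016 but 0.052 with the stricter filter), with Procr (2.32 ± 0.38) among them. In the interferon response list, 6 of 11 members were higher (median 1.12, adjusted p = 0.016 but 0.071 to 0.18 with the stricter filter or the sex block, median 0.65 with the sex block), with Oasl2 (2.79 ± 0.33) and Usp18 (2.71 ± 0.42) among them. Of the primary granule list, 4 of 9 members were lower (median -0.90, adjusted p = 0.028 but 0.055 to 0.79 with probe set means, the stricter filter or the sex block and 0.057 without GM replicate 1, median -0.08 with the sex block), with Igsf6 (-2.45 ± 0.42) among them. For mast cells and basophils, 3 of 6 members were lower (median -0.88, adjusted p = 0.028 but 0.05 to 0.66 with probe set means, the stricter filter or the sex block and 0.057 without GM replicate 1, median -0.24 with the sex block). Erythroid genes that were higher included Car2 (3.46 ± 0.47) and Gfi1b (2.08 ± 0.32), and in that list 7 of 20 members were higher (median 0.49, adjusted p = 0.2). In the monocyte list 2 of 17 members were lower (median -0.04, adjusted p = 0.63, median -0.25 to 0.09 without GM replicate 1 or 2 or GMP replicate 1). The Y-linked Eif2s3y (-6.42 ± 1.17) was lower, the groups share no sex class, and with the class as a block 1425 genes were lower. Without GM replicate 1, 464 genes were higher, and without GM replicate 2, 430 were higher and 245 lower.

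CLP (2 arrays) carried more of the early B cell genes than LMPP (5 arrays) and less of several granule genes. The B lineage factor Ebf1 (7.88 ± 0.43, adjusted p = 4.6e-16), the recombinase Rag1 (5.53 ± 0.43), the surrogate light chain Vpreb1 (4.90 ± 0.35), the receptor Il7r (4.72 ± 0.64) and the adaptor Blnk (4.03 ± 0.34, adjusted p = 1.9e-11) were higher in CLP. The granule protease Prtn3 (-5.43 ± 0.47), the chemokine Ccl9 (-4.77 ± 0.41), Hlf (-4.32 ± 0.22) and Car2 (-4.30 ± 0.43) were lower. In all, 438 genes were called higher and 2521 lower in CLP.

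Of the early B list, 11 of 14 members were higher (median 2.17, adjusted p = 0.028 but 0.054 with the floor and 0.088 without CLP replicate 1). In the early lymphoid list, 4 of 16 members were higher and 1 lower (median 0.68, adjusted p = 0.21), with Rag2 (1.47 ± 0.37) among them. Mitosis genes such as Bub1 (-3.44 ± 0.31) and Ccnb2 (-3.12 ± 0.39) were lower. Of their list, 18 of 19 members were lower (median -2.48, adjusted p = 0.27). Granule genes such as Ctsg (-3.06 ± 0.56) were lower. Of their list, 4 of 9 members were lower (median -0.89, adjusted p = 0.4). Of the stem cell list, 8 of 18 members were lower (median -0.91, adjusted p = 0.21), with Procr (-3.81 ± 0.35) among them. In the mitochondrial respiration list, 6 of 17 members were lower (median -0.94, adjusted p = 0.27), with Ndufa4 (-2.71 ± 0.36) and Atp5b (-1.74 ± 0.40) among them. Notch1 (1.36 ± 0.28) was higher and Tal1 (-1.53 ± 0.23) lower. Quantile normalization again took called genes that were higher from 14.8% to 38.2% (1142 genes). Centring each array on its median left 281 higher and moved the median of all genes by -0.19. Counts were 673 higher and 2886 lower with the LMPP arrays without Xist, which share the class of CLP, 446 and 2336 with those with Xist, and 825 genes were higher without CLP replicate 1.

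The ProB arrays (2) carried transcripts of plasmacytoid dendritic cells and many of NK and T cells at higher levels than CLP (2 arrays), and less of the early B genes Ebf1 and Rag1. Siglech (5.92 ± 0.40, adjusted p = 1.2e-14) and Bst2 (6.36 ± 0.42), markers of plasmacytoid dendritic cells, the chemokine Ccl5 (7.68 ± 0.98) and the receptor Klre1 (5.32 ± 0.55) of NK cells, and Thy1 (5.07 ± 0.40, adjusted p = 9.5e-13) and Cd3d (3.98 ± 0.35) of T cells were higher. Ebf1 (-4.90 ± 0.52, -3.05 without ProB replicate 2), Rag1 (-4.78 ± 0.52), Erg (-5.01 ± 0.43) and Cd34 (-4.67 ± 0.29) were lower. In all, 3055 genes were called higher and 1059 lower in ProB.

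Of the plasmacytoid dendritic list, 7 of 8 members were higher (median 3.34, adjusted p = 0.00054), with Pacsin1 (4.87 ± 0.24) among them. In the NK and cytotoxic list, 16 of 17 members were higher (median 4.25, adjusted p = 0.16), with Klrd1 (5.66 ± 0.74) and granzyme Gzma (7.04 ± 0.99), open to cross-hybridisation, among them. Of the T cell list, 11 of 19 members were higher (median 1.13, adjusted p = 0.16), with Cd28 (3.36 ± 0.36) among them. Class II genes such as H2-Ab1 (4.74 ± 0.49) and Cd74 (4.69 ± 0.68) were higher. Of their list, 7 of 10 members were higher and 1 lower (median 3.14, adjusted p = 0.23). In the early B list, 4 of 14 members were higher and 5 lower (median -0.16, adjusted p = 0.69, median -0.46 to 0.19 without CLP replicate 1 or 2 or ProB replicate 1 or 2), with Cd79b (2.52 ± 0.35) among them. For mature B cells 7 of 13 members were higher (8 adjusted over the list alone, median 1.17, adjusted p = 0.42, median 0.22 without ProB replicate 1 and 1.90 without ProB replicate 2), with Tnfrsf13b (3.70 ± 0.61) among them. For plasma cells, 3 of 7 members were higher (median 0.76, adjusted p = 0.26, median 1.37 without ProB replicate 1), with Jchain (6.86 ± 1.09) and Mzb1 (3.05 ± 0.52) among them. The factors Tbx21 (5.13 ± 0.27) and Eomes (4.82 ± 0.52) of cytotoxic cells were higher. The neutrophil list had a mean level of 4.57 on ProB replicate 1 and 8.01 on replicate 2. Quantile normalization again took called genes that were higher from 74.3% to 52.3%, with 1995 lower. It moved the median of all genes by -0.141, and centring on the median by 0.17. A fit of these 4 arrays alone called 568 genes lower.

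PreB (4 arrays) carried the early B and recombination genes at higher levels than ProB (2 arrays), and the NK, T cell and plasmacytoid dendritic transcripts of the ProB arrays were lower. Rag1 (6.41 ± 0.45, adjusted p = 2.3e-14), Ebf1 (5.87 ± 0.45), the B cell coactivator Pou2af1 (5.24 ± 0.31), the end-joining ligase Lig4 (5.71 ± 0.26) and Vpreb3 (4.15 ± 0.49, adjusted p = 1.3e-08) were higher in PreB. Siglech (-6.37 ± 0.34), Bst2 (-5.55 ± 0.37), Klrd1 (-6.23 ± 0.64), Ccl5 (-5.94 ± 0.85) and Thy1 (-5.20 ± 0.34) were lower. In all, 1556 genes were called higher and 1273 lower in PreB.

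Of the early B list, 14 of 14 members were higher (median 2.91, adjusted p = 0.0016). In the list of V(D)J recombination, 7 of 11 members were higher and 1 lower (median 1.94, adjusted p = 0.0016), with the polymerase Polm (3.18 ± 0.36) among them. Of the DNA replication list, 13 of 21 members were higher (median 1.10, adjusted p = 0.015 but 0.16 with probe set means), with Rrm2 (2.29 ± 0.36) and Cdc6 (2.19 ± 0.37) among them. Of the mitosis list, 13 of 19 members were higher (14 adjusted over the list alone, median 1.37, adjusted p = 0.36), Bub1 (2.67 ± 0.33) included. In the NK and cytotoxic list, 17 of 17 members were lower (median -3.97, adjusted p = 0.015). Of the T cell list, 12 of 19 members were lower (median -1.64, adjusted p = 0.00038). Of the plasmacytoid dendritic list, 7 of 8 members were lower (median -5.19, adjusted p = 3.1e-06). For the interferon response, 4 of 11 members were lower (median -0.75, adjusted p = 0.015 but 0.056 to 0.098 with probe set means or the stricter filter), with Irf7 (-3.83 ± 0.23) and Usp18 (-3.82 ± 0.39) among them. Foxo1 (2.69 ± 0.30) was higher and Tbx21 (-4.49 ± 0.23) and Irf8 (-2.32 ± 0.36) lower. The neutrophil list had a mean level of 3.81 and 4.95 on PreB replicates 1 and 2 and of 8.19 and 8.63 on replicates 3 and 4, and the NK list 3.16 and 3.38 against 5.60 and 5.92. Counts were 1670 higher and 1130 lower with PreB replicates 1 and 2, which carry Xist as ProB does, and 1777 and 1926 with replicates 3 and 4, which do not. A fit of the arrays of these groups alone called 927 genes higher and 791 lower.

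In IgM+SP (2 arrays), recombination genes and many of cell division were lower than in PreB (4 arrays), and several genes of mature and activated B cells were higher. Rag1 (-4.53 ± 0.45, adjusted p = 1.4e-09), Vpreb1 (-4.65 ± 0.37), Vpreb3 (-3.40 ± 0.49) and the cyclin Ccnb2 (-3.17 ± 0.40) were lower in IgM+SP. The activation marker Cd83 (3.76 ± 0.36, adjusted p = 9.9e-10), the complement receptor Cr2 (3.06 ± 0.36), the chemokine receptor Cxcr5 (3.04 ± 0.43), the receptor Ahr (4.69 ± 0.70) and Egr2 (4.17 ± 0.53) were higher. In all, 474 genes were called higher and 1315 lower in IgM+SP.

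Of the V(D)J recombination list, 7 of 11 members were lower (median -2.31, adjusted p = 0.0037), with Xrcc6 (-3.25 ± 0.39), Polm (-3.04 ± 0.36) and Dntt (-2.57 ± 0.44) among them. In the ribosome biogenesis list, 7 of 20 members were higher (median 0.89, adjusted p = 0.005 but 0.051 with probe set means), with Myc (2.83 ± 0.28), Tsr1 (2.45 ± 0.33) and Gnl3 (1.98 ± 0.22) among them. Of the early B list, 7 of 14 members were lower (median -1.28, adjusted p = 0.072 but 0.048 without PreB replicate 1). In the mature B list, 8 of 13 members were higher and 3 lower (median 1.11, adjusted p = 0.29). Of the mitosis list, 19 of 19 members were lower (median -2.33, adjusted p = 0.083), with Cdk1 (-3.15 ± 0.46) and Birc5 (-3.10 ± 0.58) among them. Of the DNA replication list, 11 of 21 members were lower (median -1.20, adjusted p = 0.058 but 0.036 to 0.048 without IgM+SP replicate 1 or PreB replicate 1 or 2), with Gins2 (-2.12 ± 0.35) and Tk1 (-1.91 ± 0.36) among them. Tcf3 (-2.04 ± 0.40) was lower. The stroma and endothelium list, in which 4 of 10 members were higher (median 0.25, adjusted p = 0.32 but 0.00083 without IgM+SP replicate 2, median 0.05 without IgM+SP replicate 1 and 0.40 without IgM+SP replicate 2), included the collagens Col1a1 (4.02 ± 0.76, 0.36 without IgM+SP replicate 1, 7.68 without IgM+SP replicate 2) and Col1a2 (4.09 ± 0.85, 0.10 without IgM+SP replicate 1, 8.08 without IgM+SP replicate 2). The neutrophil list had a mean level of 8.61 and 8.0 on the IgM+SP arrays. Of that list, 1 of 14 members was higher (0 adjusted over the list alone, median 1.76, adjusted p = 0.4, median 0.95 without PreB replicate 1). The percentage of called genes that were higher went from 26.5% to 39.6% with quantile normalization again. Counts were 285 higher and 620 lower with the PreB arrays without Xist, which share the class of IgM+SP, 1008 and 2537 with those with Xist, 295 and 635 with the sex class as a block, and 108 and 193 with a fit of these groups alone. Without IgM+SP replicate 1, 305 genes were higher.

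ETP (3 arrays) had more of some Notch target genes than LMPP (5 arrays) and less of several stem cell genes, though no list passed. The targets Nrarp (3.20 ± 0.25, adjusted p = 2.1e-12), Hes1 (2.92 ± 0.50) and Dtx1 (1.58 ± 0.28), the receptor Notch1 (1.82 ± 0.24) and Trat1 (2.53 ± 0.20, adjusted p = 5.4e-12) of T cells were higher in ETP, as were the mast cell protease Cpa3 (6.41 ± 0.26), the gelsolin family protein Scin (6.59 ± 0.26) and the death ligand Fasl (5.62 ± 0.32). Hlf (-4.53 ± 0.19), Meis1 (-2.80 ± 0.25), Flt3 (-2.43 ± 0.29) and the granulocyte receptor Csf3r (-2.66 ± 0.28) were lower. In all, 993 genes were called higher and 671 lower in ETP.

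Of the Notch pathway list, 4 of 11 members were higher (median 0.35, adjusted p = 0.17, median 0.53 without LMPP replicate 5). In the T cell list, 3 of 19 members were higher (median -0.02, adjusted p = 0.73, median -0.09 to 0.03 with 1 array left out), while its mean was 0.29 and its test direction upward, so median and mean differ in sign; Cd5 (1.74 ± 0.17) and Cd6 (1.36 ± 0.20) were among the higher genes. For mast cells and basophils, 2 of 6 members were higher (median 0.65, adjusted p = 0.44). Of the stem cell list, 8 of 18 members were lower (median -0.85, adjusted p = 0.11), with Ndn (-2.27 ± 0.25) among them. Mitosis genes such as Plk1 (-2.37 ± 0.46) and Aurka (-2.19 ± 0.31) were lower. Of their list, 16 of 19 members were lower (median -1.77, adjusted p = 0.38). In the early lymphoid list, 2 of 16 members were higher and 2 lower (median -0.01, adjusted p = 0.96, median -0.42 to 0.26 with 1 array left out). The neutrophil list, in which 3 of 14 members were lower (2 adjusted over the list alone, median -1.28, adjusted p = 0.81), had a mean level of 7.13 and 7.12 on LMPP replicates 4 and 5 and of 4.89 to 4.99 on replicates 1 to 3. The receptor segments Trbv1 (8.80 ± 0.45) and Trbv13-2 (4.38 ± 0.23), open to cross-hybridisation, were higher, and Cebpa (-1.46 ± 0.18) and Spi1 (-1.41 ± 0.30) were lower. Of the called genes, 59.7% were higher, and 40.6% with quantile normalization again. Counts were 828 higher and 585 lower within the arrays with Xist, and 1410 and 938 within those without, where ETP keeps 1 array that is taken to vary like the other groups.

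CD4 (2 arrays) carried the T cell receptor complex and its regulators, and the ETP arrays (3) carried more of several progenitor and granule genes. The receptor chains Cd3g (8.21 ± 0.24, adjusted p = 3.8e-25) and Cd3d (7.69 ± 0.32), the adhesion molecule Cd2 (8.19 ± 0.26), the homing receptor Ccr7 (7.90 ± 0.27) and the T lineage factor Bcl11b (6.93 ± 0.26, adjusted p = 2.4e-22) were higher in CD4. The growth factor angiopoietin Angpt1 (-7.95 ± 0.33), Mpo (-7.11 ± 0.83) and Myb (-3.75 ± 0.22) were lower. In all, 1940 genes were called higher and 1750 lower in CD4.

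Of the T cell list, 16 of 19 members were higher (median 4.12, adjusted p = 8.5e-07), with Thy1 (6.91 ± 0.36) outside the list also higher. Of the DNA replication list, 17 of 21 members were lower (median -1.79, adjusted p = 0.003 but 0.26 with probe set means, median -1.10 with probe set means), with Cdc6 (-4.12 ± 0.39) and Pole (-3.28 ± 0.31) among them. Of the mitosis list, 17 of 19 members were lower (median -2.43, adjusted p = 0.25), with Cdc20 (-3.64 ± 0.27) among them. Granule genes such as Ctsg (-4.98 ± 0.61) were lower. Of their list, 4 of 9 members were lower (median -0.80, adjusted p = 0.3, median -0.50 without CD4 replicate 2). In the interferon response list, 6 of 11 members were higher and 1 lower (median 1.12, adjusted p = 0.25), with Gbp2 (2.01 ± 0.26) and Irf7 (1.96 ± 0.25) among them. For mature B cells 8 of 13 members were higher (median 1.36, adjusted p = 0.25), with Cxcr5 (5.40 ± 0.45) and Ms4a1 (3.66 ± 0.65) among them. In the Notch pathway list 1 of 11 members was higher and 4 lower (median -0.39, adjusted p = 0.36, median -0.24 without CD4 replicate 2 and -0.21 without ETP replicate 2), with Hes1 (-3.34 ± 0.62) and Nrarp (-3.03 ± 0.31) lower and Dtx1 (3.04 ± 0.35) higher. Id3 (4.70 ± 0.31) and Foxo1 (3.37 ± 0.31) were higher and Tal1 (-2.82 ± 0.25) lower. The groups share no sex class, and with the class as a block 1273 genes were higher.

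NKmature (2 arrays) carried many cytotoxic genes at higher levels than CLP (2 arrays) and many B and lymphoid progenitor genes at lower ones. The receptor Klre1 (7.85 ± 0.55, adjusted p = 1.8e-14), the chemokine Ccl5 (8.44 ± 0.98), the factors Tbx21 (7.34 ± 0.27) and Eomes (6.12 ± 0.52) and granzyme Gzma (8.62 ± 0.99, adjusted p = 4.6e-09), open to cross-hybridisation, were higher in NKmature. Ebf1 (-8.02 ± 0.52), Dntt (-7.98 ± 0.51), Rag1 (-6.58 ± 0.52), Flt3 (-6.44 ± 0.40) and Hoxa9 (-7.05 ± 0.51) were lower. In all, 4063 genes were called higher and 1693 lower in NKmature.

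In the NK and cytotoxic list, 17 of 17 members were higher (median 6.12, adjusted p = 0.088). Of the plasmacytoid dendritic list, 5 of 8 members were lower (median -1.73, adjusted p = 0.045 but 0.05 to 0.12 with probe set means, no filter or the sex block and 0.06 without CLP replicate 1), with Ccr9 (-4.75 ± 1.28) and Cox6a2 (-3.41 ± 0.30) among them. Of the early B list, 12 of 14 members were lower (median -2.70, adjusted p = 0.051 but 0.039 to 0.047 without NKmature replicate 1 or 2), with Blnk (-5.34 ± 0.41) and Vpreb1 (-5.00 ± 0.42) among them. Of the early lymphoid list, 3 of 16 members were higher and 10 lower (median -2.99, adjusted p = 0.051 but 0.039 to 0.047 without NKmature replicate 1 or 2). Of the mitosis list, 18 of 19 members were higher (median 2.26, adjusted p = 0.56), with Ccnb2 (4.09 ± 0.47) and Aurkb (3.19 ± 0.44) among them. In the mitochondrial respiration list, 11 of 17 members were higher (median 1.54, adjusted p = 0.56), with Cox4i1 (2.10 ± 0.27) among them. The inhibitor Id2 (6.62 ± 0.84) was higher and Myb (-2.62 ± 0.24) lower. The neutrophil list, in which 10 of 14 members were higher and 1 lower (median 4.00, adjusted p = 0.77), had mean levels of 8.27 and 8.34 on the NKmature arrays, with S100a8 (7.70 ± 1.96) and Lcn2 (6.57 ± 1.27) among its higher members. Quantile normalization again took called genes that were higher from 70.6% to 50% (2544 higher, 2541 lower). The median of all genes moved by -0.242 with it, by 0.243 with centring on the median and by -0.15 with a floor of 16. With the stricter filter on dim probe sets, 1022 genes were lower.

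**Figure D2:**
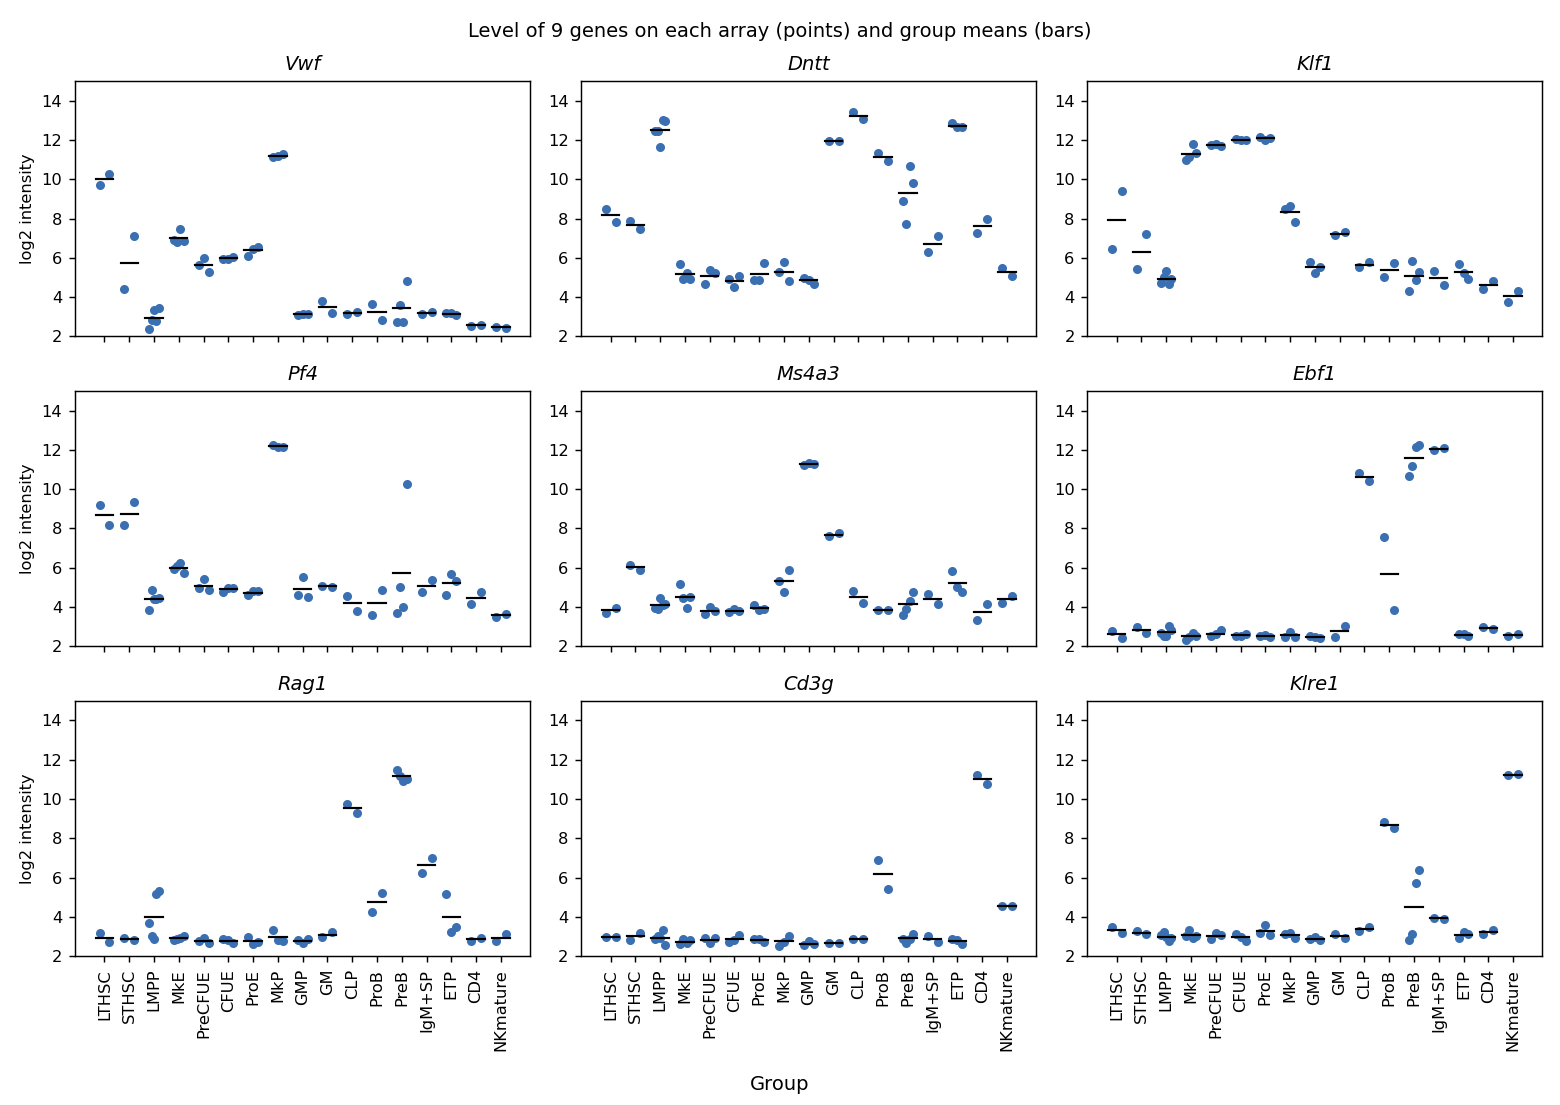
Level of 9 genes on each of the 47 arrays (log2 of the deposited intensity, one point per array, short bars at group means). Ebf1 lay at 10.6 in CLP, 5.7 in ProB (7.55 and 3.85 on its arrays) and 11.57 in PreB, and Klf1 at 11.31 in MkE against 4.94 in LMPP.

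Progenitors were also compared by 6 lineage signatures, each holding the genes called higher in that lineage's groups than in those of every other lineage on these same arrays: erythroid (490 genes, from CFUE and ProE), megakaryocyte (194, MkP), granulocyte-monocyte (205, GM), B (226, from ProB, PreB and IgM+SP), T (324, CD4) and NK (397, NKmature). Because the signatures were chosen on these samples, they are not independent evidence of a direction. The granulocyte-monocyte signature comes from GM alone, whose group mean correlated across genes, which are not independent replicates, at 0.976 with LMPP and 0.961 with GMP. It holds 6 of the 9 primary granule and 4 of the 17 monocyte genes, but also 3 of the 18 stem cell and 3 of the 16 early lymphoid ones, and Dntt, Flt3, Cd34, Hlf and Procr, named after its values were seen, are in it. In MkE against LTHSC, the granulocyte-monocyte signature was lower (median log2 difference -0.82, 88 genes lower and 16 higher, camera adjusted p = 0.0057), as was the T signature (-0.31, adjusted p = 0.0079). In LMPP against MkE, the granulocyte-monocyte signature, Dntt, Flt3 and Cd34 included, was higher (1.22, 110 genes higher and 9 lower, adjusted p = 7.7e-07), the B signature was higher (0.24, adjusted p = 0.0013) and the erythroid signature was lower (-0.56, 168 genes lower and 13 higher, adjusted p = 0.016 but 0.052 to 0.06 with the stricter filter, centring or the LMPP arrays without Xist alone). In CLP against LMPP, the granulocyte-monocyte signature was lower (-0.89, adjusted p = 0.006 but 0.093 with the stricter filter) and the B signature higher (0.21, adjusted p = 0.006). In LMPP against LTHSC, the granulocyte-monocyte signature was higher (0.41, 59 genes higher and 21 lower, adjusted p = 0.026), a call that ended without LTHSC replicate 1 or 2 (adjusted p = 0.076 for each) and without LMPP replicate 3 (adjusted p = 0.051), and with centring (0.2, median 0.23), the stricter filter (0.051), array weights (0.057) or the LMPP arrays with Xist alone (0.089). In GMP against LMPP no signature passed by camera (1 of 6, T, at an unadjusted p under 0.05; with the preset correlation the erythroid, megakaryocyte and T signatures passed), and its granulocyte-monocyte signature had 59 genes higher and 57 lower. With the preset correlation of 0.01 in place of an estimated one, 21 of the 30 tests passed in place of 8. With the sex class block, which rests on PreB here, the T and granulocyte-monocyte signatures in MkE against LTHSC had medians of -0.03 and -0.02 (adjusted p = 0.55 and 0.73). In LMPP against MkE the granulocyte-monocyte (median 0.56) and erythroid calls ended (adjusted p = 0.11 each). Median, mean and test differed in sign for the megakaryocyte signature in LMPP against LTHSC and MkE, for the granulocyte-monocyte and NK signatures in GMP against LMPP, and for the T and NK signatures in CLP against LMPP.

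**Figure D3:**
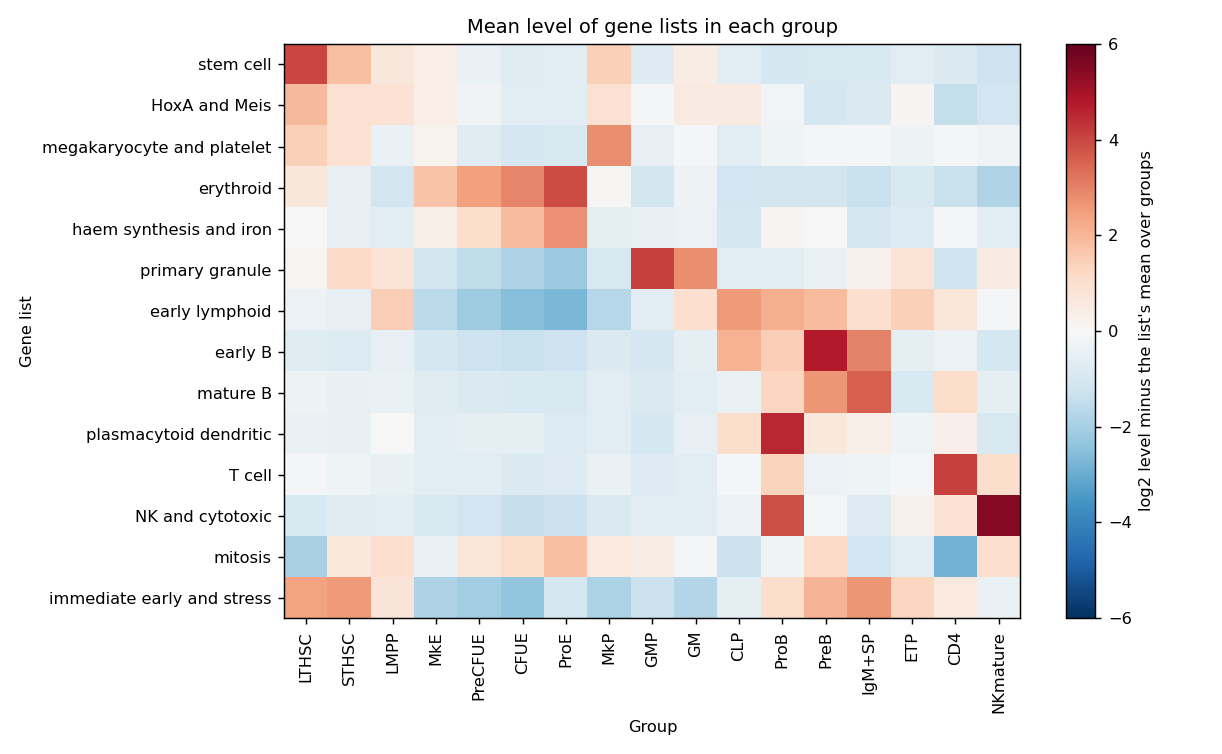
Mean log2 level of the measured genes of 14 gene lists in each of the 17 groups, each list shown as its difference from its own mean over the groups. The stem cell list was highest in LTHSC (8.90), the erythroid list in ProE (10.2), the NK list in NKmature (10.1) with ProB next (8.52), and the plasmacytoid dendritic list in ProB (10.4).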

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

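Tests here chosen after the results were seen were the exchange of a ProB label, the mature B list in PreB and both handling response tests in LMPP. So were the Xist classes behind the PreB and LMPP tests. Among 262 series of 4 or 5 values (array medians and quartiles, list levels and named genes in LMPP, MkE and PreB), 10 had a value set apart from the rest of its group, and chance sets apart about 1 in 20. In LMPP, replicate 2 had the primary granule list at 8.20, Ccl9 at 10.63 and Ms4a6c at 8.25. Replicate 3 had the V(D)J recombination list at 6.24 and Tcf4 at 9.03, replicate 1 had Hes1 at 6.31 and replicate 4 had Aqp1 at 3.63. In MkE, replicate 2 had the list for sex of the animal at 4.88, replicate 1 had H2-Aa at 5.90 and replicate 3 had Vwf at 7.47.

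Transcripts of NK cells, T cells and plasmacytoid dendritic cells stood high on both ProB arrays, with the NK genes Ccl5 and Gzma 7.68 and 7.04 (log2) over CLP, against 8.44 and 8.62 in NKmature. Of 26 genes at least 8-fold higher in CD4 than in all groups but ProB, 11.5% were called higher in ProB than PreB. Most T cell list genes were, so CD4 T cells stay open. A ProB array correlated with arrays of other groups at 0.889 at most, under the 0.962 between the ProB arrays, which argues against an exchange of a single ProB label within the series and leaves an exchange of both open. Of 32 such genes of NKmature, 65.6% were called higher, so NK cells among the sorted cells remain a candidate source. Their median share was 12.9% by the levels of these genes (quartiles 1.85 and 19.3). Plasmacytoid dendritic cells were not tested, and a biological state of the ProB cells stays open as well.

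PreB replicates 3 and 4, which lack Xist, had more neutrophil and NK transcript than replicates 1 and 2. Neutrophils alone are argued against by 1718 genes called at least 2-fold lower in replicates 3 and 4. A later stage is argued against for mature B genes, whose list had a median of -1.71 (quartiles -2.23 and -1.48). For other genes it stays open, since genes higher and lower in IgM+SP than in ProB had medians of 0.543 and -0.842, the early B list -0.993 and the mitosis list -1.39, and replicates 3 and 4 correlated with IgM+SP replicate 2 at 0.964 and 0.960, against 0.898 and 0.900 for replicates 1 and 2. A batch that follows Xist stays open, since the correlation across genes of -0.402 with the LMPP difference set PreB arrays with Xist alone beside LMPP arrays with both Xist and Eif2s3y, and neutrophils as part of the difference and the sex of the animals may contribute.

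LMPP replicates 1 and 2 differ from replicates 3 to 5 in Xist. The immediate early and stress list was higher in replicates 1 and 2 by a median of 3.34, but replicate 3 lay at -0.484 from replicates 1 and 2 and at 4.81 from replicates 4 and 5. This argues against a handling response as what sets replicate 3 apart from replicates 1 and 2, and it may account for part of what sets replicates 4 and 5 apart. A batch shared with the ETP arrays of the same classes stays open, since the correlation across genes of -0.317 rests on 1 ETP array without Xist, whose immediate early list lay at 6.0 against 9.30 and 9.68 on the others. No biological explanation was tested.

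Other splits of the same arrays were tried for comparisons with at least 3 arrays per group. For genes called, only the real split gave as many in LMPP against MkE (1 of 100 splits, 1761 genes, highest other 1357) and PreCFUE against MkE (1 of 35, 1020, 502). So it was in MkP against MkE (1 of 35, 1606, 1087), GMP against LMPP (1 of 56, 2350, 1383) and ETP against LMPP (1 of 56, 1664, 1231). This argues against chance in these 5 (unadjusted), not against a batch. For list tests passed, chance is argued against in LMPP against MkE (1 of 100, 2, 1), PreCFUE against MkE (1 of 35, 2, 0) and GMP against LMPP (1 of 56, 8, 3). It stays open for lists in MkP against MkE (2 of 35, 1, 1) and for signatures in LMPP against MkE (4 of 100, 3, with 5 in another split). In ETP against LMPP 0 lists passed (highest other 4) and in GMP against LMPP 0 signatures (highest other 0), so all 56 splits had as many by construction and nothing was tested. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. CFUE against PreCFUE had 370 genes (as many in 1 split, highest other 2) and 0 lists (10 splits, highest other 0). ProE against CFUE had 644 genes (1 split, highest other 1) and 2 lists (1 split, highest other 0).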

How the results depend on the processing

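The fits that use the sex-linked classes, and the B signature without ProB, were chosen only after the results were seen. Counts of called genes (higher or lower in the first group), of list tests and of signature tests that moved by over 1.5 times are given here, with camera adjusted p in parentheses after a signature. A floor of 16 before log2, no filter on dim probe sets, a trended robust spread and the B signature without ProB moved no count that far. The cause of the changes was not tested, beyond fewer arrays or genes in some fits and the PreB part in the sex class block, given above. Among the genes the naming rule takes, 64 were no longer called with the mean of all probe sets, 89 with the compared groups alone, 50 with the sex class as a block and 20 or fewer under each other setting run on all comparisons. With the mean of all probe sets of a gene in place of the brightest, STHSC against LTHSC had 186 higher and 371 lower, LMPP against STHSC 226 higher and MkE against LTHSC 693 higher. LMPP against MkE had 566 lower, PreCFUE against MkE 246 higher and 392 lower and CFUE against PreCFUE 129 lower. ProE against CFUE had 159 higher and 233 lower, MkP against MkE 234 higher and 726 lower and GMP against LMPP 937 higher. CLP against LMPP had 255 higher and 1674 lower, ProB against CLP 572 lower and IgM+SP against PreB 306 higher. ETP against LMPP had 577 higher. In that fit 30 list tests passed (from 46). With the stricter filter on dim probe sets, NKmature against CLP had 1022 lower. In that fit 5 signature tests passed (from 8). The granulocyte-monocyte signature in LMPP against LTHSC (0.051), the erythroid signature in LMPP against MkE (0.06) and the granulocyte-monocyte signature in CLP against LMPP (0.093) no longer passed. With quantile normalization again, MkP against MkE had 728 higher and 638 lower, CLP against LMPP 1142 higher and ProB against CLP 1995 lower. NKmature against CLP had 2544 higher and 2541 lower. With each array centred on its median, CLP against LMPP had 281 higher. The granulocyte-monocyte signature in LMPP against LTHSC (0.2) and the erythroid signature in LMPP against MkE (0.055) no longer passed. With array weights (0.312 to 11.2, from a fit that stopped before convergence), STHSC against LTHSC had 182 higher and 358 lower and CFUE against PreCFUE 245 higher. The granulocyte-monocyte signature in LMPP against LTHSC (0.057) no longer passed. With a fit of the compared groups alone, STHSC against LTHSC had 1 higher and 2 lower, LMPP against STHSC 152 higher and 74 lower and ProB against CLP 568 lower. PreB against ProB had 927 higher and 791 lower and IgM+SP against PreB 108 higher and 193 lower. Among the lists chosen for a comparison, 16 calls ended with the mean of all probe sets, 11 with the sex class as a block (and 1 turned direction), 10 with the stricter filter, 6 with a replicate block, 3 each with centring and with the floor, 2 with quantile normalization again and 1 with no filter. Those of the replicate block were early B in CLP against LMPP (0.052), plasmacytoid dendritic in GMP against LMPP (0.1), primary granule (0.056) and mast cell (0.053) in GM against GMP, and DNA replication and sex of the animal in ProE against CFUE (0.059 each). With a preset correlation, 166 list tests and 21 signature tests passed (from 46 and 8). Replicate numbers are shared by all groups, but none of the 7 comparisons with at least 3 shared numbers had every correlation of same-numbered deviations over 0.1. Of 42 pairs, 16 correlated best with their own number, and the numbers were not taken to pair the arrays. As a replicate block they left 305 genes higher in LMPP against STHSC and gave the granulocyte-monocyte signature in LMPP against LTHSC an adjusted p = 0.059, and moved no other count that far and no other passing signature. With the sex class as a block, LMPP against STHSC had 330 higher, MkE against LTHSC 2973 lower and LMPP against MkE 2428 higher and 1831 lower. ProE against CFUE had 1398 higher and 892 lower, GM against GMP 1425 lower and IgM+SP against PreB 295 higher and 635 lower. CD4 against ETP had 1273 higher. In that fit 72 list tests passed (from 46). The erythroid and granulocyte-monocyte signatures in LMPP against MkE (0.11 each) no longer passed. The sign turned with it in MkE against LTHSC for Hoxa9 (1.02) and Pf4 (0.09), in LMPP against MkE for Csf1r (-0.02) and Lyz2 (-2.01). In ProE against CFUE it turned for Eif2s3y (-0.56), Xist (1.15) and Kdm5d (-2.11), in GM against GMP for Eif2s3y (0.98), Gfi1 (0.50), Gzmb (1.82) and Cd14 (1.29), in PreB against ProB for Mmp8 (-1.0). The test direction turned for the granulocyte-monocyte (0.73) and T (0.55) signatures in MkE against LTHSC and, at a median of 0.18, for the sex of the animal list in ProE against CFUE (adjusted p = 0.73). With the LMPP arrays without Xist alone, LMPP against STHSC had 196 higher and 130 lower, CLP against LMPP 673 higher and ETP against LMPP 1201 lower. The erythroid signature in LMPP against MkE (0.052) no longer passed. With the LMPP arrays with Xist alone, LMPP against STHSC had 990 higher and 554 lower. The granulocyte-monocyte signature in LMPP against LTHSC (0.089) no longer passed. With the PreB arrays with Xist alone, IgM+SP against PreB had 1008 higher and 2537 lower. With the PreB arrays without Xist alone, PreB against ProB had 1926 lower and IgM+SP against PreB 285 higher and 620 lower. Mmp8 in PreB against ProB lay at -1.0 with the PreB arrays with Xist alone. With single arrays left out, where a lone array is taken to vary like the other groups, 246 counts stayed within 1.5 times and 11 did not. Those results ranged over CFUE against PreCFUE higher 107 to 297, CLP against LMPP higher 436 to 825, GM against GMP higher 430 to 664, GM against GMP lower 245 to 430. IgM+SP against PreB higher 305 to 645, LMPP against STHSC higher 181 to 768, STHSC against LTHSC higher 157 to 309, STHSC against LTHSC lower 220 to 951 and MkE against LTHSC higher 719 to 1753 were the other ranges. The granulocyte-monocyte signature in LMPP against LTHSC ran from an adjusted p = 0.022 to 0.076, and Ighm in MkE against LTHSC from -6.24 without LTHSC replicate 1 to 0.66 without LTHSC replicate 2. Dim signal limits what can be compared, since genes with no group mean over 3.889 (log2) were not tested.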

Other observations

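The comparisons of PreB with CLP and of GM with LMPP were chosen only after the results were seen. PreB (4 arrays) against CLP (2 arrays) leaves out the ProB arrays. The B cell genes Spib (7.59 ± 0.26, adjusted p = 1.6e-23), Ms4a1 (6.88 ± 0.61) and Pou2af1 (6.55 ± 0.31) were higher in PreB by limma, and Cd34 (-5.22 ± 0.25), Flt3 (-5.17 ± 0.35) and Hoxa9 (-6.23 ± 0.44) were lower. For early B genes 10 of 14 members were higher (median 2.61, adjusted p = 0.22), for mature B genes 10 of 13 members were higher (median 3.23, adjusted p = 0.22), and for mitosis 17 of 19 members were higher (median 2.26, adjusted p = 0.41). For immediate early genes 11 of 14 members were higher (median 2.60, adjusted p = 0.71). For neutrophil genes, whose levels on PreB replicates 3 and 4 were 8.19 and 8.63 against 3.81 and 4.95 on the others, 3 of 14 members were higher and 1 lower (0 adjusted over the list alone, median 1.52, adjusted p = 0.86). In all, 3489 genes were called higher and 1461 lower (3975 and 1646 with the PreB arrays with Xist, 3205 and 1540 with those without, 2267 and 2341 after quantile normalization again).

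GM (2 arrays) against LMPP (5 arrays) had more granule transcript, and the groups share no sex class, so that a batch going with it cannot be told apart from the group. The genes Ms4a3 (3.56 ± 0.29, adjusted p = 3.3e-11), F13a1 (4.95 ± 0.50), Cpa3 (4.07 ± 0.30) and Car1 (4.43 ± 0.51) were higher in GM by limma, and for primary granule genes 5 of 9 members were higher (6 adjusted over the list alone, median 2.09, adjusted p = 0.019). The Y-linked Eif2s3y (-5.14 ± 1.07) and Kdm5d (-3.32 ± 0.77, its probe sets from -3.32 to 0.08) and the immediate early and related Egr1 (-4.14 ± 0.98), Klf4 (-3.10 ± 0.75) and Klf2 (-3.08 ± 0.81) were lower. For immediate early genes, whose list was low on LMPP replicates 4 and 5, 7 of 14 members were lower (11 adjusted over the list alone, median -2.48, adjusted p = 0.14), and for mitosis 7 of 19 members were lower (9 adjusted over the list alone, median -1.04, adjusted p = 0.14). In all, 487 genes were called higher and 114 lower (437 and 140 with the LMPP arrays with Xist, 988 and 235 with those without, 236 and 158 after quantile normalization again).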
